A study of Homo sapiens with 7 samples.

How the data were processed

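The assay was a lentiviral massively parallel reporter assay (MPRA) in HepG2, a human liver carcinoma cell line. In this assay each test element drives a reporter that carries a transcribed barcode, the constructs integrate into the genome, and barcode RNA over barcode DNA measures the activity of the element. Per the labels' protocols, each oligonucleotide held a test element of 170 nucleotides between flanks of 15 nucleotides on either side. A separate amplification gave each orientation, and the forward and reverse pools were mixed in equal amounts. Cells were seeded in wells, infected, and harvested after 48 hours, with 8 wells and 16 RNA columns for each of 3 replicates. The data comprise 3 DNA libraries, 3 RNA libraries and 1 plasmid library in which barcodes were read together with their elements. The labels do not say whether the replicates came from separate infections on separate days, so the p-values measure the spread between these libraries, which may be technical.

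The deposited tables of each DNA and RNA library hold whole-number counts per element and orientation, per the file headers. The authors' deposited signal table pools the replicates, and its total counts equalled the sum of the 3 libraries at all 135736 listed element copies. Its normalized columns are CPM by the authors, summing to 1000000 per molecule. Its ratio column, also by the authors, was recovered from the values as RNA CPM over DNA CPM with a pseudocount of 0.01 added to each. The deposited signal is the log2 of that ratio, per the file headers and the values. The deposited association table lists barcodes of 15 bases with the element each was assigned to. The submitters' processing notes name BWA 0.7.17 and the genome build hg38 without a role for either. Whether reads or molecular identifiers were counted, and which barcodes were filtered, is not given in the sources used here. Floors therefore cover counting error only. Bootstrap intervals resample elements, so they describe the spread across elements and not that between libraries. They treat elements as independent, although elements with neighbouring numbers had similar activity, so they may be too narrow.

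Elements are named by a number and an orientation in these tables. Here "sequence" means a numbered element, and "copy" means that sequence in one orientation. No coordinates, bases, classes or control elements were tied to the numbers in the tables used here. The planned comparisons of element classes, of altered with parent elements, of motifs, base composition and distance to transcription starts, and of elements near listed genes were therefore not made, nor was activity centred on negative controls.

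Total counts were 44258011, 34955412 and 34860651 in the DNA libraries and 114738370, 110005047 and 108324310 in the RNA libraries. One count was worth 0.0226 to 0.0287 CPM in DNA and 0.00872 to 0.00923 CPM in RNA. The 100 most abundant copies took 0.387% to 0.398% of the counts of a DNA library and 1.38% to 1.44% of those of an RNA library. Every pair of libraries of the same molecule differed by more than sampling noise, with a chi-square per degree of freedom of 3.00 to 3.45 between DNA libraries and 5.86 to 6.60 between RNA libraries, so no pair was within sampling noise, as repeat deposits of one library would be. Library preparation noise alone could give such values, so this says nothing of separate cultures.

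Activity was tested per copy with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the deposited counts. Library sizes were the totals over all copies, scaled by TMM factors, with group (RNA or DNA) as the only term and robust dispersion. Copies with at least 10 counts in each DNA library were tested, a filter that does not look at RNA. A call is an adjusted p (Benjamini-Hochberg) under 0.05. The log2 fold change is relative to the centre set by TMM and not to inactive elements. The orientation difference was tested in the same tool as the interaction of molecule with orientation, with forward and reverse counts of a library as separate columns of the same library size, over sequences that passed the filter in both orientations. A positive value means higher RNA/DNA in the forward copy. Standard errors are the log2 fold change over the square root of the F statistic. CPM are scaled by library totals alone, so the ratio of a copy's printed CPM lies below its TMM-scaled fold change. Activities and orientation differences per replicate, with their SD, are log2 of (RNA CPM + 1) over (DNA CPM + 1) after TMM scaling of the CPM, of libraries with the same number, which understates the change of rare copies. Correlations over all tested copies, between replicates and of the mean log2 ratio with the deposited signal, used CPM scaled by library totals alone; those between orientations of different replicates used the TMM-scaled values.

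Both tests were tried on simulated data drawn from the means and library sizes of the real copies, with 50 features changed at each fold. For activity, over 134435 copies, edgeR recovered 8% at 1.25-fold, 76% at 1.5-fold, 100% at 2-fold and 100% at 4-fold, with 11 false calls. For the orientation difference, over 66769 sequences, it recovered 0% at 1.25-fold, 26% at 1.5-fold, 92% at 2-fold and 100% at 4-fold, with 6 false calls. The simulation used a single constant dispersion and left nearly all features unchanged. Far more features were called in the real data, where the same adjusted p is reached at a less strict raw p. These rates and false calls therefore do not carry over to the real tests.

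By a rule set before the data were examined, the text names at most 2 copies or sequences with the largest and 2 with the smallest log2 fold change in each comparison, among those called and with the same direction in all 3 replicates. Alternatives were other library scaling (RLE factors, library size alone), no DNA filter, at least 50 DNA counts, at least 10 barcodes, a fold of at least 2, each replicate left out, the replicate number as a block, DESeq2 1.42.0, limma 3.58.1, and for correlations a pseudocount of 0.1. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.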

Results

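The library was designed to address how ChIP-seq signal and transcription factor binding relate to regulatory activity in HepG2 cells. It was measured as RNA and integrated DNA in 3 replicates each, at 34860651 to 44258011 counts per DNA library and 108324310 to 114738370 per RNA library. The tables listed 135736 copies of 68115 sequences, with codes up to 69210. The labels give 138420 oligonucleotides, 2 times the highest code. If that number counts each sequence once per orientation, which the labels do not say, 98.1% of copies were listed. Of the listed sequences, 67621 were listed in both orientations, 209 only forward and 285 only reverse. The DNA filter kept 134435 copies, and 66769 sequences passed it in both orientations. A copy had a median of 291 counts in DNA replicate 1 and of 587 counts in RNA replicate 1.

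The plasmid library held 12452483 barcodes, and none was assigned to more than 1 copy. A copy carried a median of 86 barcodes (quartiles 58 and 119, range 1 to 542). Forward copies carried a median of 82 barcodes and reverse copies 89. The spread of activity between replicates fell with barcode number. The median SD of log2 RNA/DNA (n = 3) was 0.22 for the 1550 tested copies with 1 to 9 barcodes, 0.15 for the 58776 copies with 50 to 99, and 0.10 for the 3996 copies with 200 or more. The pseudocount of 1 CPM lowers the SD of rare copies, so that of copies with few barcodes may be understated. The share of copies called, in either direction, was 46.3%, 66.5% and 79.8% in these barcode groups. Activity itself was nearly unrelated to barcode number, with a Spearman correlation across copies of 0.00164; copies are not independent replicates.

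Element values repeated closely between replicates. Across the tested copies, Pearson's r of log2(CPM + 1) was 0.959 to 0.966 between DNA libraries (Spearman 0.957 to 0.965) and 0.984 to 0.986 between RNA libraries (Spearman 0.980 to 0.982). For log2 RNA/DNA, which carries the noise of both molecules, r was 0.923 to 0.931 and Spearman's correlation 0.876 to 0.881. These correlations describe the measurement, and no p is given because copies are not replicates. The share of copies with RNA/DNA at least 2-fold above the TMM centre was 14.9% ± 0.224 (SD, n = 3) per replicate.

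The first comparison asked which elements raised barcode RNA over integrated DNA. The values formed a main body below the TMM centre and a long shoulder of active elements above it. RNA/DNA was at least 2-fold above the centre, and called, for 23778 copies (17.7%), at least 4-fold for 2925 (2.18%) and at least 8-fold for 240 (0.179%). The lower side was short, with 656 called copies (0.488%) at least 2-fold below. With no minimum fold, edgeR's quasi-likelihood test called 47285 copies (35.2%) higher and 43248 (32.2%) lower of 134435, and 43902 (32.7%) were not called. The middle 90% of copies lay between a log2 RNA/DNA of -0.74 and 1.72, with quartiles of -0.41 and 0.65 and a median standard error of 0.12.

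How many copies counted as higher or lower depended on where the centre was placed. With TMM the median log2 RNA/DNA was -0.04, and 52.2% of calls were higher. With library size alone the median was -0.47, and 32618 copies were called higher against 78686 lower (29.3% higher). With the centre at the mode of the distribution, at -0.36 on the TMM scale, a choice made after seeing the data, the counts were 67749 and 11735 (85.2% higher). The count at least 2-fold higher was 13067 with library size alone and 33971 with the centre at the mode. The count at least 2-fold lower was 18451 with library size alone and 50 with the centre at the mode. It rested on replicates as well, at 1524 without replicate 1 and 1044 without replicate 3, and was 27 with limma.

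**Figure D1:**
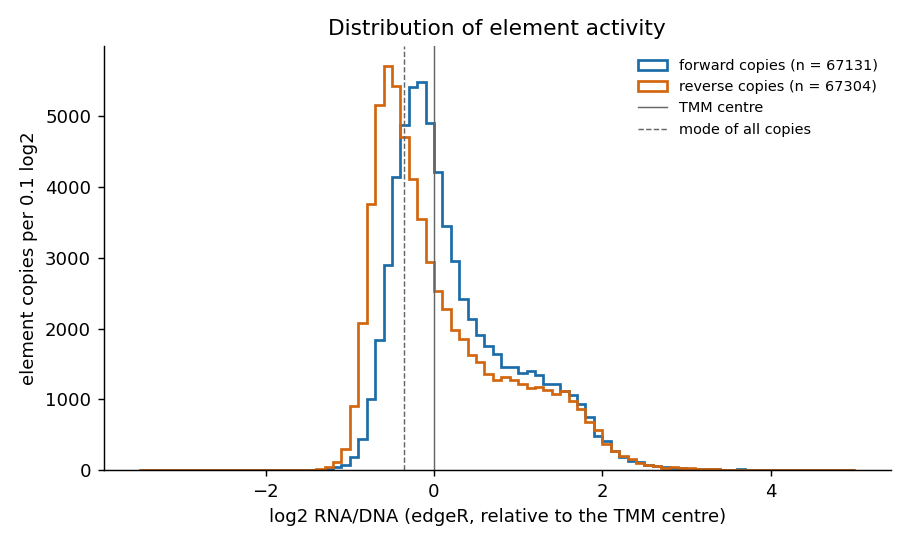
Histogram of log2 RNA/DNA per copy from the edgeR fit, in steps of 0.1 (x axis, log2; y axis, number of copies), for 67131 forward and 67304 reverse copies. Vertical lines mark the TMM centre and the mode of all copies at -0.36; the main body of forward copies lies to the right of that of reverse copies, with medians of 0.05 and -0.17, and the active shoulders overlap, with 95th percentiles of 1.73 and 1.72.

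With all libraries, the copy with the highest log2 RNA/DNA was Seq_68079_fwd, with 83 barcodes. It had 8.61 ± 2.68 CPM in DNA and 160 ± 9.31 CPM in RNA (SD, n = 3), scaled by library totals alone. Its TMM-scaled log2 fold change was 4.65 (SE 0.14, adjusted p = 1.59e-21 by edgeR), and 4.23 with library size alone. Its reverse copy was also among the active ones, at 4.19 (SE 0.18). Next was Seq_54000_rev, with 40 barcodes, 3.59 ± 2.43 CPM in DNA and 58.1 ± 2.79 CPM in RNA (SD, n = 3). Its log2 fold change was 4.47 (SE 0.41, adjusted p = 0.000404 by edgeR), and its DNA counts were uneven, at 95, 78 and 223. Without DNA replicate 3, an alternative chosen after seeing the data, its fold rose from 22.2 to 35.6, and its log2 fold change of 5.16 then ranked above that of Seq_68079_fwd, at 4.93. The order was also turned without replicate 3 of both molecules (5.18 and 4.92). The 2 lowest copies rested on few barcodes. Seq_68544_rev had 1 barcode and DNA counts of 34, 20 and 10 against RNA counts of 2, 4 and 8, a log2 fold change of -3.24 (SE 0.62, adjusted p = 2.18e-05 by edgeR). That value was -2.53 without replicate 1, -4.16 without replicate 3 and -0.47 by limma on values with a pseudocount, and all counts of copies with 1 barcode were even. Its count of 10 in DNA replicate 3 is the lowest that passes the filter. If such counts were overstated, this copy would not have been tested with all libraries. Seq_68895_fwd had 3 barcodes, 1.04 ± 0.0926 CPM in DNA and 0.150 ± 0.0141 CPM in RNA (SD, n = 3), and a log2 fold change of -2.35 (SE 0.39, adjusted p = 2.09e-06 by edgeR), or -0.69 by limma.

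The second comparison asked whether a sequence acted alike in both orientations. Activity in one orientation went with activity in the other. Of 66769 sequences, 12302 were called at least 2-fold higher as the forward copy and 11333 as the reverse copy, and 9100 (13.6%) were so in both, against 2088 for independent lists of these sizes. The 9100 made up 62.6% of the 14535 sequences at least 2-fold higher in either orientation. With library size alone 4312 sequences were at least 2-fold higher in both, 49.6% of the 8685 in either. Both lists come from the same 6 libraries, with different barcodes and no shared counts. Across sequences, log2 RNA/DNA of forward and reverse copies had a Pearson's r of 0.854 and a Spearman correlation of 0.770. Between different replicates r was 0.821 for forward against reverse, 0.915 for forward against forward and 0.942 for reverse against reverse. Divided by the geometric mean of the last 2 values, the correlation between orientations was 0.885. Replicates share the barcodes of a copy and orientations do not, so effects of the barcodes may lower this value.

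**Figure D2:**
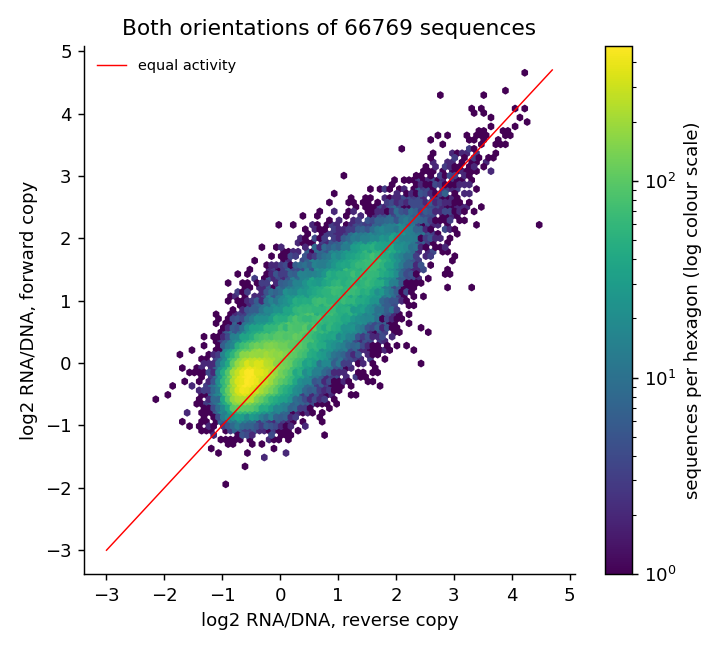
Log2 RNA/DNA of the reverse copy (x axis) and the forward copy (y axis) of 66769 sequences, as hexagons coloured by the number of sequences on a log scale. The line marks equal activity; the 2 orientations have a Pearson's r of 0.854, and the dense body of weakly active sequences lies above the line.

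Where the orientations differed, the forward copy was more often the higher. The interaction test called 16494 sequences (24.7%) higher as the forward copy and 5125 (7.68%) higher as the reverse copy, while 45150 (67.6%) were not called. Forward and reverse copies carry different barcodes, so for a single sequence a call cannot be told apart from an effect of its barcodes. At least 2-fold differences were called for 1494 and 442 sequences, and for 561 and 241 by limma on values with a pseudocount. The median forward minus reverse difference was 0.18 log2, a 1.13-fold difference, and as log2 ratios with a pseudocount it was 0.15 ± 0.01 (SD, n = 3) per replicate. Counts of calls depended on the number of libraries. They were 10971 forward and 3227 reverse without replicate 1, and 10614 and 3235 without replicate 2. When each difference was tested against the median difference of all sequences, a choice made after seeing the data, 7774 sequences were higher as the forward copy and 9156 as the reverse copy, and 593 and 1068 at least 2-fold. That test removes the general shift by construction.

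The median shift varied with activity. In 10 equal bins of the mean activity of both orientations, numbered from the lowest, the median difference was 0.19 in bin 1 (95% bootstrap interval 0.17 to 0.19), 0.24 in bin 2 and 0.27 in bins 3 and 4. It was 0.24, 0.21, 0.15, 0.12 and 0.05 in bins 5 to 9 and -0.01 in bin 10 (interval -0.02 to 0.00). Forward and reverse calls were 1984 and 169 in bin 4, 1855 and 983 in bin 8, and 1108 and 1127 in bin 10. Calls of at least 2-fold differences were 38 forward and 11 reverse in bin 1, 113 and 11 in bin 4, 211 and 42 in bin 6, 288 and 107 in bin 8, 220 and 121 in bin 9, and 69 and 57 in bin 10. Among the 14535 sequences at least 2-fold higher in either orientation, 6551 (45.1%) had a called difference between orientations, with a median difference of 0.04. Among the other 52234, a difference was called for 15068 (28.8%), with a median difference of 0.21. The groups were formed from the same counts as the test. A high value in either orientation favours a large difference and brings more RNA counts, so the contrast of these shares is partly built in.

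A change of side with orientation was less common. Copies of 1466 sequences were called higher than DNA as forward and lower as reverse, and those of 181 sequences the opposite, and the interaction was called for all 1647. Calls of opposite sign in the same counts make a called interaction nearly certain, so this adds no separate support. These numbers move with the centre. A group that overlaps the 1647 was at least 2-fold higher in 1 orientation and not called higher in the other, with a called interaction: 475 sequences for the forward and 199 for the reverse copy.

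With all libraries, the sequence with the largest forward excess was Seq_23739, with a log2 RNA/DNA of 2.24 (SE 0.10) forward and -0.03 (SE 0.11) reverse, a difference of 2.27 (SE 0.15, adjusted p = 2.57e-15 by edgeR's interaction test). Without replicate 2 that of Seq_56992 was larger (2.38 against 2.28). Seq_56992 had 1.33 (SE 0.17) forward and -0.90 (SE 0.19) reverse, a difference of 2.22 (SE 0.25, adjusted p = 5.12e-09 by edgeR), on 17 and 30 barcodes, and 1.57 by limma on values with a pseudocount. With all libraries the largest reverse excess was that of Seq_45325, with -0.02 (SE 0.15) forward and 2.42 (SE 0.09) reverse, a difference of -2.44 (SE 0.14, adjusted p = 1.61e-16 by edgeR). Seq_54000 was active in both orientations, at 2.22 (SE 0.13) forward and 4.47 (SE 0.41) reverse, with a difference of -2.25 (SE 0.49, adjusted p = 0.00763 by edgeR) that includes the uneven DNA counts of its reverse copy. Its reverse excess was larger than that of Seq_45325 without DNA replicate 3 (-2.83 against -2.50) and without replicate 3 of both molecules (-2.97 against -2.57), and by limma both were at -2.32.

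The DNA libraries were also compared with each other along activity. DNA replicate 3 was higher at strongly active elements. Binned by RNA over the DNA of the library left out of the ratio, the median log2 of DNA replicate 3 over DNA replicate 1 was -0.03 below a log2 activity of -0.5, 0.08 between 1.5 and 2, and 0.40 (95% bootstrap interval 0.38 to 0.42) at 3 or above, over 314 copies. DNA replicate 3 over DNA replicate 2 gave 0.36 in that top bin, and DNA replicate 2 over DNA replicate 1 gave 0.06 (interval 0.01 to 0.08). In a fit without DNA replicate 3, chosen after seeing the data, log2 RNA/DNA rose by a median of 0.13 among the 240 copies at 3 or above, and 309 copies were at least 8-fold higher, against 240 with all libraries.

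**Figure D3:**
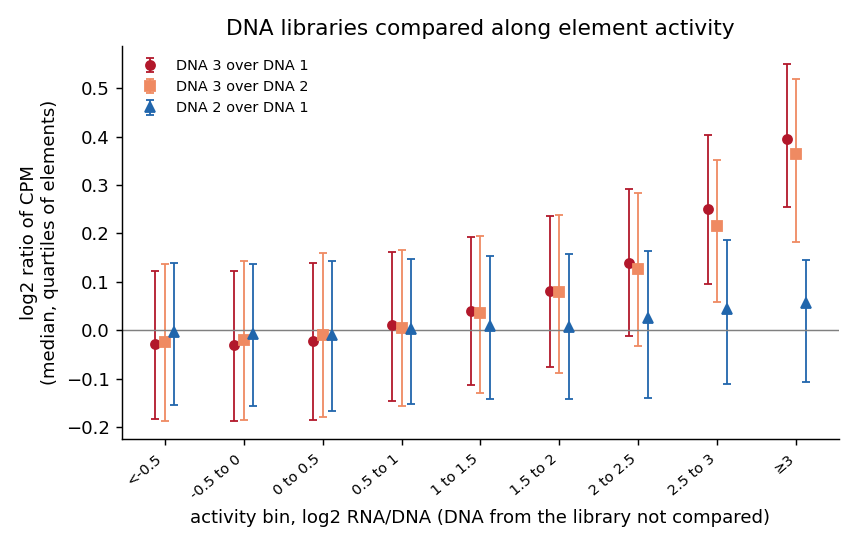
Log2 ratio of CPM between pairs of DNA libraries (y axis) by bin of log2 RNA/DNA (x axis), where the DNA of the bin comes from the library that is not in the ratio. Points are medians over copies and bars are quartiles; both ratios with DNA replicate 3 rise to 0.40 and 0.36 in the bin at 3 or above, where DNA replicate 2 over DNA replicate 1 stays at 0.06.

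The log2 ratios computed here were set against the authors' deposited signal. Across tested copies, Pearson's r was 0.992 for the mean log2 ratio per replicate and 0.99994 for the edgeR log2 fold change. All rest on the same counts, so these values check the calculation only. The deposited signal minus that fold change had a median of -0.43, since the signal is scaled by library totals alone. In the authors' deposited table the signal had a median of -0.47, and 13335 copies (9.82%) had a signal of 1 or more. Of the 100 highest deposited signals, 10 belonged to copies with no DNA count in any library and 22 to copies below the DNA filter used here.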

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

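RNA counts were present in copies that the DNA filter kept out of the main tests. They entered only the refits with no DNA filter. In 127 listed copies no DNA library had a count, and 100 of them had RNA counts, which is the observation that drew attention here. Summed over the RNA libraries these had a median of 8 counts and at most 64. A count of 0 in the pooled DNA libraries allows up to 3 counts. At the depth of the pooled RNA libraries that corresponds to 8.76 counts, and 45 copies exceeded this while the others did not. The limit takes RNA and DNA CPM to be equal. With library size alone, 13067 tested copies were called at least 2-fold higher in RNA. An active copy with up to 3 DNA counts could exceed the limit, so exceeding it does not show RNA without DNA. Of the 127 copies, 102 carried 1 barcode, and all nonzero counts of copies with 1 barcode were even. If each of those counts stood for 0.5 as many, 29 copies would exceed the limit, which covers counting error only. The highest value of the authors' deposited signal, 4.34, belonged to a copy with no DNA count. RNA over DNA has no finite value there.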

How the results depend on the processing

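The settings that leave out DNA replicate 3 alone, set the centre at the mode, test against the median difference, block by library, or require a 2-fold orientation difference were chosen after seeing the data. Named copies and sequences kept direction and an adjusted p under 0.05 in all 100 refits in which they were tested. Counts of activity calls with no minimum fold kept within 1.5 times under RLE, DESeq2, limma, the DNA and barcode filters and each replicate left out. Exceptions were lower copies with library size alone (78686) or the centre at the mode (11735), and a 2-fold minimum (23778 higher, 656 lower). With that minimum, lower copies were 1524 without replicate 1, 1044 without replicate 3 and 27 with limma. They were 18451 with library size alone and 50 with the centre at the mode. Orientation calls moved to 7774 forward and 9156 reverse against the median difference, and to 1494 and 442 with a 2-fold minimum. Leaving out replicates gave 10614 to 11192 forward and 3227 to 3878 reverse; fewer libraries are the construction of that setting. The median orientation difference was 0.15 by limma, on values with a pseudocount. Mean r of log2 RNA/DNA between replicates was 0.927, with 0.931 at 50 or more DNA counts, 0.911 with a pseudocount of 0.1, and 0.923 to 0.931 for single pairs. The correlation with the authors' signal was 0.992, and 0.99978 without a pseudocount on counts pooled over replicates, over 135609 copies with RNA and DNA. The last value was near 1 by construction, since the signal is such a ratio of the same pooled counts, with a pseudocount of 0.01. The cause of the shifts in r between replicates was not tested. Assigning barcodes to a single element changed nothing, as all were.

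With the replicate block, activity calls were 47394 higher and 43446 lower, and orientation calls 16622 and 5174, so it changed no count by over 1.5 times. Deviations of DNA and RNA libraries with the same number correlated at 0.0345, 0.0459 and 0.0516. Each library correlated best with its own number, a hint from the data. Other pairs gave -0.0348 to -0.00957. Deviations are from the mean of the libraries of a molecule, so positive values at the same number make other pairs negative on balance. The libraries were taken to share only a number. Without DNA replicate 3 activity calls were 45691 and 41593, and orientation calls 14220 and 4632. Centring on negative controls and all settings for altered against parent elements were not run, since no such elements are named. Precision went with depth. Copies with 1 to 9 barcodes had a median DNA count of 43.7 and a median SD of log2 RNA/DNA of 0.22. With 200 or more barcodes these were 687 and 0.10. The pseudocount lowers the SD of rare copies more, so the contrast may be understated.

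Of the 10 splits of the 6 libraries into groups of 3, the real one called 90533 copies and was the 1 split with that many, and the highest other called 0. Of the 4 ways to exchange orientation labels between replicates, the real one called 21619 sequences, again 1 way alone, and the highest other called 0. Both sets are too few for a share under 0.05. Every other split also mixes RNA and DNA libraries in each group, so real differences become spread within groups. Exchanging the labels of a replicate does the same for orientation. Counts near 0 were therefore built in and lend no support.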

Other observations

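The tests on DNA replicate 3 and on the forward excess were chosen after the result was seen. The 2 tests on the order of codes were set before their results, but the ranges of codes were chosen afterwards.

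Activity was strongly structured along the numbers that name the sequences. In stretches of 1000 codes, the median log2 RNA/DNA of both orientations ran from -0.41 to 1.28. Codes 1 to 31000 had a median of 0.48, with 25.5% of sequences at least 2-fold higher in both orientations, but it held both the highest and the lowest of these stretches, at 1.28 (codes 7001 to 8000) and -0.41 (codes 21001 to 22000). Codes 31001 to 56000 had a median of -0.28 with 2.47% of sequences at that level, and codes 56001 to 66000 had -0.31 with 2.43%. The last range, 66001 to 69210, had 21.7% at that level, and its stretches differed as well. In codes from 68001 on, even codes had a median of 1.27 and odd codes 0.24, while over all codes the medians were -0.08 for both. Seq_68079_fwd, the copy with the highest activity when all libraries are used, lies there, at an odd code. The 2 lowest named copies, Seq_68544_rev and Seq_68895_fwd, lie there as well. Without DNA replicate 3, Seq_54000_rev is higher than Seq_68079_fwd (5.16 against 4.93).

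Neighbouring codes were also alike within a stretch. After the median of each stretch was removed, the correlation between a code and the next was 0.124 in codes 1 to 31000 and did not fade, at 0.123 for codes 20 apart. In codes 31001 to 56000 it was 0.417 for adjacent codes, 0.231 at 2 apart and 0.115 at 3 apart. In codes 56001 to 66000 it was 0.801, falling to 0.561 at 5 apart and to -0.0426 at 20 apart. In the last range, codes 2 apart were more alike (0.822) than adjacent ones (0.623). Over all codes the adjacent correlation was 0.288, against at most 0.0346 in 100 shuffles within stretches, which argues against a chance order. Removing barcode number and DNA count left 0.284, which argues against similar abundance as the source. A candidate explanation that stays open is that codes follow the design of the library, with short runs of related sequences and a last set arranged in pairs. The bases or coordinates behind the codes would decide it, and no such test was made.

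DNA replicate 3 was higher where RNA was higher. Across 25 bins of activity its share over that of DNA replicate 1 followed a straight line in RNA over DNA (R2 0.996), with a slope of 4.79% (95% bootstrap interval 4.67% to 4.90%), against 0.561% (0.437% to 0.714%) for DNA replicate 2. Intercept and slope sum to about 1 by the scaling of CPM, so that part of the test decides nothing. Lower depth is argued against by DNA replicate 2, of nearly the same depth, whose log2 excess in the most active bin was 0.0563, and an exchange with an RNA library by correlations of at most 0.735 with RNA and at least 0.959 with DNA. The values are consistent with counts derived from RNA making up about that slope of this library, in excess of DNA replicate 1; how they may have come about was not tested. No biological explanation was tested, since the design gives none.

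The median forward excess was present over most of the range of activity and absent at its top. One constant factor is argued against by the lowest and highest of 10 bins of activity, whose median log2 differences lie 0.19 apart. A constant added background from forward constructs would give an equal linear difference at every level. The median linear difference in RNA/DNA was 0.0807 in bin 1, 0.124 to 0.157 in bins 3 to 8, 0.0779 in bin 9 and -0.0180 in bin 10. The ratio of bin 10 to bin 1, -0.224, argues against one background over the whole range, while bins 3 to 8 were nearly level. What stays open, as untested, includes an added background over part of the range, any strand-specific property of the sequences and a bias of barcode assignment between the pools.

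Copies with 1 barcode showed a further irregularity. All 3051 of their nonzero counts were even, with 0 odd counts. With 2 barcodes 45.3% of counts were odd, and with 3 barcodes 50.4%. Mean DNA counts per barcode were 23.0 in copies with 1 barcode, against 3.05 in copies with 51 to 100 barcodes. That excess was graded and not particular to 1 barcode, at 14.2 with 2 barcodes, 14.1 with 3 and 6.93 with 6 to 10. Of the 662 copies with 1 barcode, 201 passed the DNA filter.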
